A study of Rattus norvegicus with 8 samples.

How the data were processed

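The neurohypophysis, also called the neural lobe or posterior pituitary, was profiled by RNA sequencing in male Sprague Dawley rats of 35 days (n = 4 libraries) and 125 days (n = 4). Per the labels' protocols, the animals were perfused with saline under anaesthesia, the lobe was frozen, and poly(A)-selected libraries were made with an NEBNext Ultra II kit. Group and replicate number were taken from the sample labels. The labels number the samples of each age without stating that each came from a separate animal, so p-values measure the spread between these samples, which may in part be technical.

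The deposited table lists 33294 genes by symbol, with 8 library columns and 2 columns of the authors' means, which equal the mean of the 4 libraries and were not used further. Its values are a depth-normalized signal: gene read counts that the authors divided by 1 size factor per library, as read from the values, since 100% of values were whole multiples of the smallest nonzero value in their library (tolerance 0.001 reads). The submitters' processing notes list Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.13, featureCounts from Subread 2.0.1, DESeq2 1.34.0 and build rn7, without roles or order. The annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and members of multigene families such as the RT1, haemoglobin, Mcpt and Lyc genes, which share reads with near-identical copies, are uncertain. The reference gene table used here was of the assembly GRCr8, which differs from the build of the files, so it served only for names and for which genes neighbour each other, and no coordinates are given.

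Recovered read totals ran from 28429133 to 58696254 per library, and the size factors from 0.793 to 1.77. No batch, litter or date was labelled. No 2 libraries looked like copies: between libraries of 1 age the variance over genes was 4.26 to 66.0 times that of read sampling. Floors and the bound for a gene at 0 (3 reads over the group) cover counting error only.

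The main test was planned for values that are not raw counts: limma (version 3.58.1, in R 4.3.3) with an intensity trend, on log2(value + 1), for 17919 genes with a value of at least 10 in at least 4 of the 8 libraries. Age was the only term, tests were two-sided, and calls were made at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are log2 values, 125 minus 35 days, given with their standard error (SE); on the log2(value + 1) scale the change of low genes is understated. Depth-normalized counts are given as mean ± SD.

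Before the data were examined, 26 lists were fixed: 15 gene groups and 11 lists of cell type markers. For each, members past the threshold were counted over all genes tested and adjusted over the list alone. Each list was compared with the other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. The named genes follow a rule fixed at the same time: the 8 largest rises and 8 largest falls among called genes with a symbol (no LOC or RGD identifier), non-overlapping ages and a mean of at least 100, up to 4 members with the lowest adjusted p from lists with at least 3 calls or a camera call, every call in lists with fewer, and Avp, Oxt, Gfap, Rax, Cntf, Gh1, Prl and Pomc. A gene that this rule names is not reported here. Members named because they went against the rest of their list, or to complete a short count, were chosen after their values were seen. Marker levels per library (mean log2(value + 1)) were compared by a two-sided exact permutation test of 4 against 4, with 70 arrangements and a smallest possible p of 0.0286.

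Alternatives fixed at the same time were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, 3 other scalings, no trend, library weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, the anterior lobe marker level as a covariate, and leaving out each library. List counts without 35-day replicate 3 and with the anterior lobe covariate, and a fit on the 5 libraries with the lowest anterior lobe level, were chosen after seeing the data. On data simulated for the comparison of 125 with 35 days (17732 genes), the test recovered 84 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 9 false calls among 219. Simulated genes were independent and no library stood apart, unlike in the real data. The genes changed 2-fold and 4-fold were drawn from those with a mean of at least 50. These rates may therefore not carry over to the real libraries. Figures were drawn with matplotlib 3.10.9.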

Results

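Gene expression in the neural lobe, which holds the axon terminals of the hypothalamic vasopressin and oxytocin neurons, their glia (pituicytes) and a dense capillary bed, was compared between male rats of 35 and 125 days to ask how it changes with age. Each age had 4 libraries, with 28429133 to 58696254 recovered reads each, and 35-day replicate 4 was the deepest. Of 33294 genes listed, 6832 were at 0 in all 8 libraries. The first principal component (53.4% of variance) separated the ages. The second (21.3%) set 35-day replicate 3 (-59.7) apart from the other 35-day libraries (21.8 to 29.3).

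In limma, 34 of 35 proliferation genes, 28 of 40 matrix genes, 13 of 18 endothelial markers and 10 of 15 pericyte and smooth muscle markers were lower at 125 days, and against other genes the matrix and vascular lists had adjusted p = 0.48 with an estimated correlation. The opioid precursor gene Pdyn, the neurotrophin gene Bdnf, the class II antigen presentation genes Cd74 and RT1-Da and 11 of 23 immediate early and heat shock genes were higher. Pdyn rose from 1264 ± 123 to 6449 ± 646 depth-normalized counts (SD, n = 4), a log2 change of 2.35 (SE 0.11, adjusted p = 3.15e-06). Top2a, a topoisomerase of dividing cells, was at 2055 ± 112 at 35 days and 251 ± 25.9 at 125 days (log2 change -3.03, SE 0.10, adjusted p = 8.67e-07). Gfap, the intermediate filament of astrocytes and pituicytes, was at 3295 ± 471 and 1074 ± 150 (log2 change -1.62, SE 0.14, adjusted p = 6.37e-05). Across the 17919 genes tested with limma, 3174 (17.7%) passed the threshold, 1585 higher and 1589 lower at 125 days, and 1244 of these changed at least 2-fold (499 higher, 745 lower). Without 35-day replicate 3 the count was 5495 (2846 higher, 2649 lower), and it was 1978, 1948 and 1894 without 125-day replicates 1, 3 and 4.

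**Figure D1:**
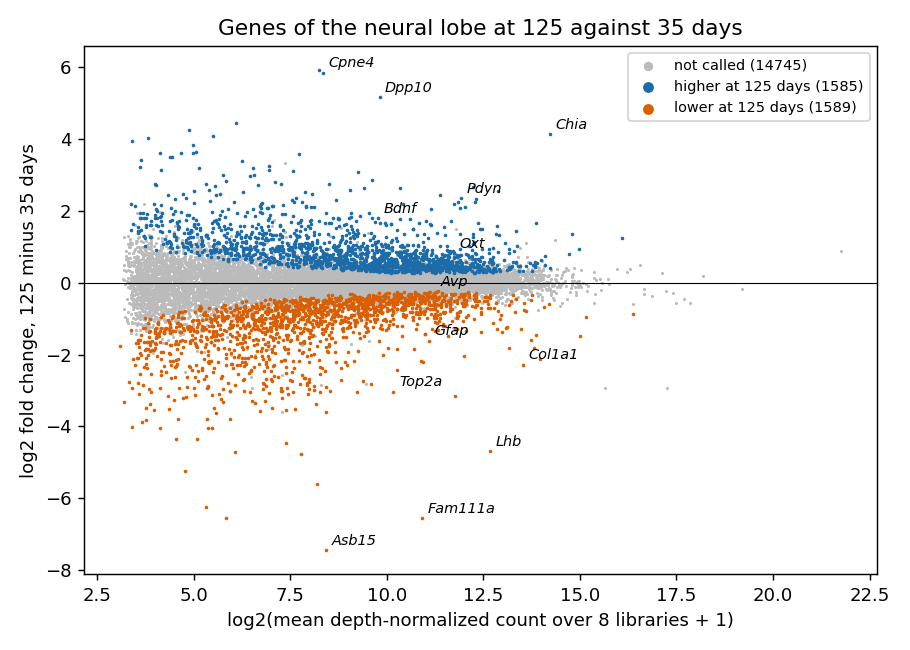
Log2 fold change (125 minus 35 days, limma) against log2 of the mean depth-normalized count plus 1 for the 17919 genes tested, with 1585 genes called higher in blue, 1589 called lower in orange and the rest in grey. The called genes lie on both sides of 0, from Asb15 at -7.44 upward, with Cpne4 at 5.84.

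Among genes for neuropeptides and dense-core vesicle proteins, 7 of 19 measured members rose and 1 fell (7 and 2 adjusted over the list alone), and without 35-day replicate 3 the counts were 11 and 1. Besides Pdyn, the prohormone convertase gene Pcsk1 rose 1.57 (SE 0.15) on the log2 scale, from 3771 ± 756 to 11043 ± 1259. Chgb, a granin, rose 1.25 (SE 0.29), a call lost without 125-day replicate 4 (adjusted p = 0.0517). Pcsk2 rose 0.79 (SE 0.19), a call lost with the anterior lobe level as a covariate (log2 change 0.52, SE 0.22, adjusted p = 0.146) and without 125-day replicates 1 (0.0640) and 4 (0.0605). The member that fell was Vgf (log2 change -1.64, SE 0.48), which was chosen after its values were seen, as were the other members named here for going against their list. This call was lost with the replicate block (0.0569), with the anterior lobe covariate (log2 change -0.65, SE 0.43, adjusted p = 0.350) and without 35-day replicate 2 or any 1 of the 125-day libraries (0.0676 to 0.108). Oxt, encoding oxytocin, was at 2461 ± 564 and 4398 ± 1199 (log2 change 0.82, SE 0.21, adjusted p = 0.0235). Its ages overlapped, and the call was lost without any 1 of 6 libraries, at adjusted p from 0.0511 to 0.0678, all but 35-day replicate 3 and 125-day replicate 1. Avp, encoding vasopressin, was at 2604 ± 446 and 2261 ± 676 (log2 change -0.24, SE 0.22, adjusted p = 0.502). Pituitary endocrine cells also express the granin and convertase genes of this list. In the same libraries Pomc, a hormone precursor gene of the intermediate lobe list, took 5.65 to 6.78% of 35-day replicates 1, 2 and 4 and 10.2% of replicate 3. It took 10.1 to 14.3% of each 125-day library. Against other genes the list passed the camera threshold (adjusted p = 0.0155), but not without 35-day replicate 1 (0.0622) or 4 (0.0726), and with adjusted p = 0.48 with an estimated correlation.

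Of 21 genes of the synaptic vesicle and release machinery, 8 rose and 1, Stx1a, fell (10 and 1 adjusted over the list alone; 12 and 2 without 35-day replicate 3). The Stx1a call (log2 change -0.41, SE 0.11) was lost with the replicate block (0.0504), with the covariate (log2 change -0.43, SE 0.15, adjusted p = 0.0755) and without any 1 library but replicate 3 of either age (0.0534 to 0.0669). Syt4, a synaptotagmin, rose from 16213 ± 3018 to 40767 ± 5623 (adjusted p = 4.96e-04). Complexin 1 (Cplx1) rose 0.92 (SE 0.14), Cadps, which primes dense-core vesicles, 0.67 (SE 0.12) and the vesicle glycoprotein gene Sv2a 0.53 (SE 0.09). By camera the adjusted p was 3.58e-04, and adjusted p = 0.48 with an estimated correlation. These libraries do not show whether the reads came from axon terminals or from pituitary endocrine cells. The Pomc share was 5.65 to 10.2% at 35 days and 10.1 to 14.3% at 125 days.

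Growth-associated and axonal cytoskeleton genes went both ways, 5 of 30 higher and 5 lower (5 and 6 adjusted over the list alone; 8 and 9 without 35-day replicate 3; camera adjusted p = 0.688). Gap43, of growth cones, rose 1.05 (SE 0.15) and Mapt, encoding tau, 1.07 (SE 0.15), while Marcks fell by 0.83 (SE 0.13). Sprr1a was at 0.272 ± 0.545 at 35 days, with reads in 1 library, and at 18.9 ± 10.4 at 125 days. In the trophic list 2 of 30 rose and 5 fell (2 and 6 adjusted over the list alone; 2 and 5 without 35-day replicate 3; camera adjusted p = 0.725). Bdnf rose 1.79 (SE 0.15), from 396 ± 77.4 to 1357 ± 124, and Hgf rose 0.61 (SE 0.17). The Hgf call was lost with the replicate block (0.0574), with the covariate (log2 change 0.26, SE 0.15, adjusted p = 0.289) and without 35-day replicates 2 or 4 or any 1 of the 125-day libraries (0.0524 to 0.0923). The growth factor genes Igf1 (log2 change -1.32, SE 0.19) and Igf2 (from 3537 ± 960.2 to 1365 ± 73.1) fell, as did the neurotrophin receptor gene Ntrk3 (-1.29, SE 0.17). The list's median change was 0.09 and its mean -0.08, the sign of the camera test. Cntf, encoding ciliary neurotrophic factor, was at 115 ± 10.5 and 107 ± 19.8 (log2 change -0.11, SE 0.17, adjusted p = 0.696). Of 34 guidance and growth-inhibitory genes, 8 fell and Lingo1 rose (9 and 1 adjusted over the list alone; 14 and 1 without 35-day replicate 3). The proteoglycan genes Acan (log2 change -2.49, SE 0.50), Ncan (-1.41, SE 0.29) and Bcan (-0.93, SE 0.18) fell, and so did the guidance receptor gene Robo2 (-0.89, SE 0.14). That list's camera adjusted p was 0.124, and 0.00158 without 35-day replicate 3, where it was adjusted p = 0.433 with an estimated correlation.

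**Figure D2:**
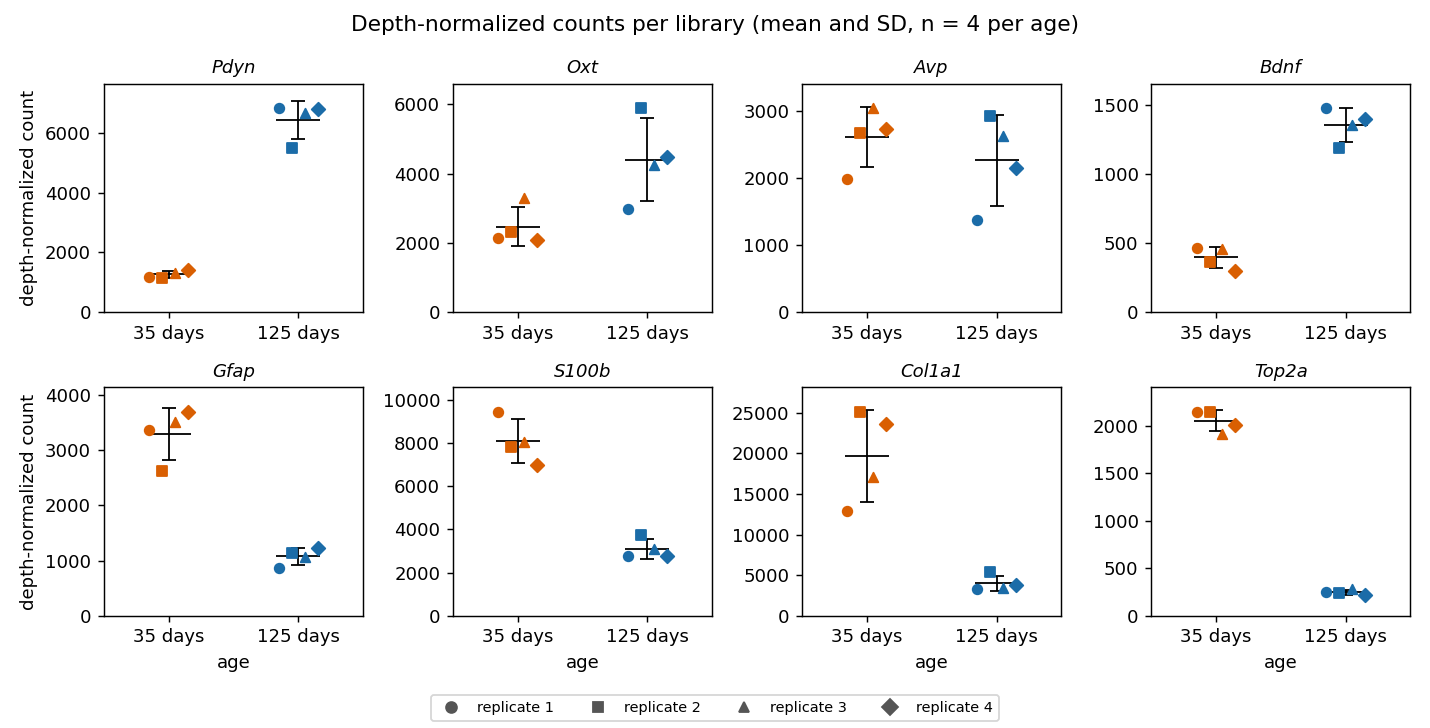
Depth-normalized counts of 8 genes in each library by age, with the mean and SD (n = 4 per age) in black and a symbol for each replicate number. Pdyn and Bdnf are higher at 125 days in every library, Gfap, S100b, Col1a1 and Top2a lower in every library, while the ages overlap for Oxt and Avp.

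Proliferation genes fell most uniformly: 34 of 35 were lower (34 adjusted over the list alone, and 34 without 35-day replicate 3), with a median log2 change of -2.20, and Tyms alone did not pass (-0.13, SE 0.10, adjusted p = 0.392, and 0.0438 with library weights). Rrm2 fell from 275 ± 24.5 to 33.4 ± 2.50, and the mitotic spindle genes Prc1 (log2 change -2.73, SE 0.12) and Nusap1 (-2.71, SE 0.15) fell as well. This list passed camera (adjusted p = 2.33e-38) and kept its call, at adjusted p = 0.0191 with an estimated correlation, but not in that test without 35-day replicate 1 (0.0501) or 125-day replicate 2 (0.0541).

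Of 40 matrix genes, 28 fell (31 adjusted over the list alone; 32 without 35-day replicate 3), with a median log2 change of -0.97. Col1a1, of fibrillar collagen I, was at 19702 ± 5674 and 3986 ± 980 (log2 change -2.29, SE 0.23, adjusted p = 1.59e-04). The genes Fbn2 (log2 change -2.82, SE 0.28), Postn (-1.51, SE 0.13) and Sparc (-1.48, SE 0.15) fell too. The list passed camera at adjusted p = 1.79e-14, and had adjusted p = 0.48 with an estimated correlation. Endothelial markers fell in 13 of 18 (14 lower and 1 higher adjusted over the list alone; 14 without 35-day replicate 3), among them Egfl7 (log2 change -0.82, SE 0.17), Ramp2 (-0.92, SE 0.20), Erg (-0.76, SE 0.17) and Pecam1 (-0.98, SE 0.22). The Ramp2 call was lost with the anterior lobe covariate, where its SE was larger (log2 change -0.84, SE 0.27, adjusted p = 0.0606), and 8 of the 18 fell in that fit. The endothelial list median was -0.75 in the main fit and -0.84 with the covariate. Of 15 pericyte and smooth muscle markers 10 fell and Myh11 rose (12 and 1 adjusted over the list alone; 13 and 1 without 35-day replicate 3), with Kcnj8 at -1.26 (SE 0.20), Tagln at -0.91 (SE 0.16), Higd1b at -1.10 (SE 0.23) and Acta2 at -0.69 (SE 0.14). The Higd1b call was lost with the same covariate (log2 change -0.999, SE 0.31, adjusted p = 0.0549). The Myh11 call (log2 change 0.77, SE 0.22) was lost there too (log2 change 0.37, SE 0.22, adjusted p = 0.295), and without 35-day replicates 1 or 2 or any 1 of the 125-day libraries (0.0510 to 0.0934). Fibroblast markers fell in 8 of 16 and Aldh1a2 rose (9 and 2 adjusted over the list alone; 8 and 2 without 35-day replicate 3), with Mgp at -1.25 (SE 0.21), Clec3b at -1.07 (SE 0.18), Cdh11 at -1.02 (SE 0.16) and Lum at -0.99 (SE 0.16). The Aldh1a2 call (log2 change 1.06, SE 0.32) was lost with the replicate block (0.0532), in edgeR (0.0645) and without any 1 library but 35-day replicate 3 and 125-day replicate 2 (0.0880 to 0.124). Camera adjusted p were 2.47e-05, 3.85e-05 and 0.0119 for these 3 lists, each with adjusted p = 0.48 with an estimated correlation, and the fibroblast call was lost without 35-day replicate 3 (0.0513).

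Of 22 pituicyte markers 6 fell and Crym rose (7 and 1 adjusted over the list alone; 12 and 1 without 35-day replicate 3). Besides Gfap, S100b was at 8068 ± 1022 and 3090 ± 448 (log2 change -1.39, SE 0.13), and the water channel gene Aqp4 fell by 1.22 (SE 0.22). Pcp4 fell by 0.70 (SE 0.15), a call lost with the anterior lobe covariate (log2 change -0.59, SE 0.19, adjusted p = 0.0644). Rax, a transcription factor gene of pituicytes, was at 2013 ± 413 and 1895 ± 528 (log2 change -0.11, SE 0.20, adjusted p = 0.766). In the camera test the adjusted p was 3.08e-04, and adjusted p = 0.48 with an estimated correlation. By library, the mean level of the pituicyte, endothelium and mural lists differed between ages by -0.50, -0.63 and -0.67 (exact permutation p = 0.0571 each, adjusted 0.114), and 125-day replicate 2 had the highest level of the 125-day libraries in all 3.

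**Figure D3:**
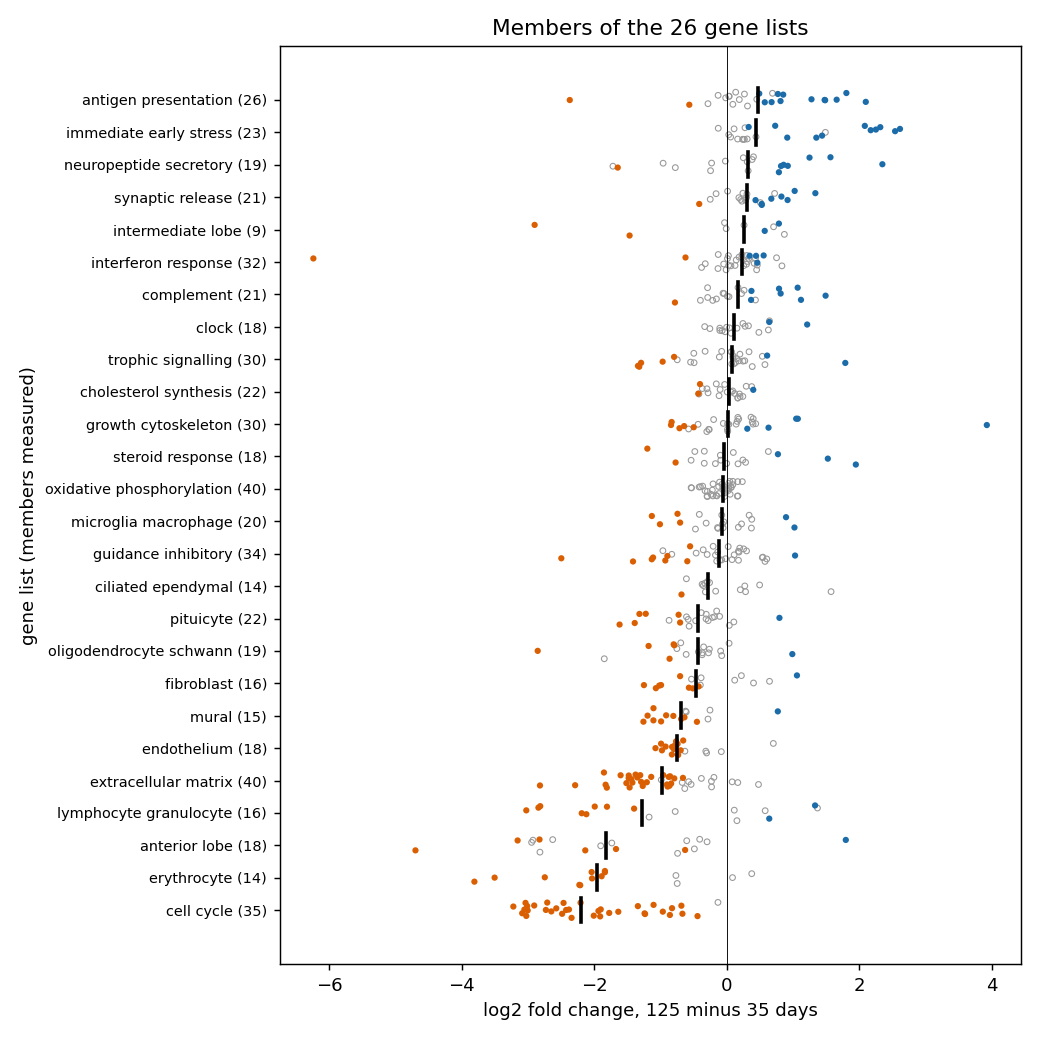
Log2 fold change (125 minus 35 days) of each measured member of the 26 lists, filled where the member passed the threshold (blue higher, orange lower) and open otherwise, with the list median as a black bar and lists ordered by it. The cell cycle list has the lowest median (-2.20) and antigen presentation the highest (0.47).

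Antigen processing and presentation genes rose in 12 of 26 and fell in 2 (14 and 2 adjusted over the list alone; 19 and 2 without 35-day replicate 3). Cd74, the class II invariant chain, was at 2914 ± 616 and 8072 ± 978 (log2 change 1.49, SE 0.15, adjusted p = 1.93e-04). The class II gene RT1-Da rose 1.48 (SE 0.17) and RT1-S3 0.81 (SE 0.09), while RT1-T24-1 (log2 change -2.37, SE 0.33) and RT1-N3 (-0.56, SE 0.15) fell. The RT1-N3 call was lost with the replicate block (0.0603), with the covariate (log2 change -0.63, SE 0.20, adjusted p = 0.0640) and without 35-day replicates 1 or 4 or 125-day replicates 1, 2 or 4 (0.0579 to 0.0971). RT1 genes share reads with near-identical copies, so their separate values are uncertain. Camera gave an adjusted p of 2.52e-04, and adjusted p = 0.48 with an estimated correlation. Complement genes rose in 7 of 21 and Cd55 fell (7 and 1 adjusted over the list alone; 8 and 1 without 35-day replicate 3; camera adjusted p = 0.0898, and adjusted p = 0.729 with an estimated correlation), with C4a up 1.49 (SE 0.16), C4b 1.07 (SE 0.19), C3 0.81 (SE 0.16) and Cfb 0.79 (SE 0.16). Without 125-day replicates 1 and 4 the complement list passed camera (0.0102 and 0.0485), but not at adjusted p = 0.4997 and 0.634 with an estimated correlation. C4a and C4b are near-identical copies, and the C3 call was lost with the anterior lobe covariate (log2 change 0.59, SE 0.19, adjusted p = 0.0650). That of Cd55 was lost without 125-day replicate 3 (0.0517).

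Interferon-stimulated genes rose in 4 of 32 and fell in 2 (4 and 2 adjusted over the list alone; 10 and 3 without 35-day replicate 3; camera adjusted p = 0.0922, and adjusted p = 0.731 with an estimated correlation). Without 35-day replicate 4 or 125-day replicate 1 this list passed camera (0.0369 and 0.0383), but not at adjusted p = 0.659 and 0.594 with an estimated correlation. Dhx58 rose 0.44 (SE 0.10) and Ddx58 0.46 (SE 0.13), calls lost with the anterior lobe covariate at log2 changes of 0.41 (SE 0.14, adjusted p = 0.0736) and 0.23 (SE 0.14, adjusted p = 0.284), and Dhx58 also without 35-day replicate 2 (0.0508) or 125-day replicate 3 (0.0524). The Ddx58 call was also lost without 35-day replicate 2 or any 1 of the 125-day libraries (0.0649 to 0.0949), and Ifitm3 fell by 0.62 (SE 0.12). Ifit1 was at 77.9 ± 29.5 at 35 days and at 0 in all 4 libraries of 125 days, at least 99.2-fold higher at 35 days against a floor of 3 reads over the group. The list median, 0.23, was the same with Ifit1 at that bound, and the mean was -0.00. Among 20 microglia and macrophage markers 4 fell and 2 rose (4 and 2 adjusted over the list alone; 6 and 2 without 35-day replicate 3; camera adjusted p = 0.476). The microglial genes Tmem119 (from 606 ± 144 to 274 ± 44.7) and P2ry12 (log2 change -1.01, SE 0.15) fell, Lyve1 fell by 0.70 (SE 0.15) and Fcgr2b rose 1.02 (SE 0.18). Of 16 lymphocyte and granulocyte markers 8 fell and 2, Cd4 and Cd8a, rose (9 and 3 adjusted over the list alone; 8 and 3 without 35-day replicate 3). The mast cell gene Cpa3 (log2 change -3.02, SE 0.32), S100a9 (-2.84, SE 0.39), Cd79b (-1.99, SE 0.30) and Mpo (-1.81, SE 0.24) fell. The Cd8a call (log2 change 1.33, SE 0.35) was lost with the covariate, where its SE was larger (log2 change 1.53, SE 0.47, adjusted p = 0.0521), and without any 1 library but 35-day replicate 3 and 125-day replicate 1 (0.0514 to 0.0789). For this list the camera adjusted p was 0.00326, and adjusted p = 0.48 with an estimated correlation.

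Immediate early and heat shock genes rose in 11 of 23 (12 adjusted over the list alone; 14 without 35-day replicate 3). Fosb was at 193 ± 65.1 and 1175 ± 439 (log2 change 2.62, SE 0.31), Fosl2 rose 2.25 (SE 0.28), Nr4a2 2.17 (SE 0.29) and Btg2 1.35 (SE 0.21). Their camera adjusted p was 2.12e-06, and adjusted p = 0.48 with an estimated correlation. Of 18 steroid response genes 3 rose and 2 fell (3 and 4 adjusted over the list alone; 3 and 5 without 35-day replicate 3; camera adjusted p = 0.985, with the median at -0.04 and the mean at 0.09). Pgr, the progesterone receptor gene, rose 1.53 (SE 0.28) and the mineralocorticoid receptor gene Nr3c2 0.77 (SE 0.12), while Mt1 fell by 0.77 (SE 0.15). Esr2 rose 1.95 (SE 0.50), a call lost with the anterior lobe covariate (log2 change 1.14, SE 0.56, adjusted p = 0.202) and without 35-day replicate 1 or any 1 of the 125-day libraries (0.0511 to 0.0652), and Esr1 fell by 1.20 (SE 0.34). The Esr1 call was lost with that covariate too (log2 change -0.36, SE 0.23, adjusted p = 0.337), and without 35-day replicates 2 or 4 or any 1 of the 125-day libraries (0.0579 to 0.1004). Of the clock genes Nfil3 and Hlf rose 1.22 (SE 0.37) and 0.64 (SE 0.18), of 18 measured (0 adjusted over the list alone; 2 without 35-day replicate 3), and both calls were lost with the covariate, Nfil3 with as large a change (1.26, SE 0.50, adjusted p = 0.121) and Hlf with a smaller one (0.39, SE 0.21, adjusted p = 0.243). Without 1 library, the Nfil3 call held only without replicate 3 of either age (otherwise 0.0882 to 0.139), and the Hlf call was lost without 35-day replicates 1 or 2 or 125-day replicates 1, 3 or 4 (0.0507 to 0.105). Of 22 cholesterol synthesis genes, Hmgcs1 (log2 change -0.43, SE 0.10) and Cyp51 (-0.40, SE 0.10) fell and Stard4 rose 0.40 (SE 0.12), and all 3 calls were lost with the covariate. There Hmgcs1 was at -0.32 (SE 0.12, adjusted p = 0.110), Cyp51 at -0.30 (SE 0.13, adjusted p = 0.139) and Stard4 at 0.31 (SE 0.16, adjusted p = 0.218). The Hmgcs1 call was lost without 125-day replicate 3 (0.0584), that of Cyp51 without 35-day replicate 2 or 125-day replicates 2, 3 or 4 (0.0501 to 0.0786), and that of Stard4 without 35-day replicates 1 or 2 or 125-day replicates 1, 3 or 4 (0.0736 to 0.125). Adjusted over the list alone, 2 fell, and without 35-day replicate 3, 2 rose and 3 fell. The median of that list was 0.04 and its mean -0.01; the camera adjusted p were 0.354 for the clock list and 0.816 for this list. None of 40 respiratory chain genes passed in limma, also adjusted over the list alone, with 3 lower at an unadjusted p below 0.05; edgeR called 0 and DESeq2 called 2 lower. Without 35-day replicate 3, 13 of them rose and the list lay above other genes (camera adjusted p = 0.0411, and adjusted p = 0.824 with an estimated correlation), whereas with all libraries its median was -0.05 (adjusted p = 0.354, and adjusted p = 0.899 with an estimated correlation). Without 35-day replicate 4 it lay below them (0.0176, and adjusted p = 0.797 with an estimated correlation).

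Transcripts of the neighbouring lobes were present in all libraries. Of 18 anterior lobe markers 6 fell and Crhr1 rose (10 and 1 adjusted over the list alone; 8 and 1 without 35-day replicate 3; 3 and 1 with the anterior lobe level as covariate). That covariate is the mean of these same markers, so the loss of calls in that fit is largely built in. The gonadotropin genes Lhb (log2 change -4.69, SE 0.59) and Fshb (-3.15, SE 0.55) and the receptor gene Gnrhr (-2.82, SE 0.44) fell, while Crhr1 rose 1.80 (SE 0.23). Gh1, encoding growth hormone, took 0.0112, 0.358, 2.68 and 0.260% of the 35-day libraries and 0.0250, 0.00392, 0.0943 and 0.0773% of the 125-day libraries (log2 change -2.92, SE 1.52, adjusted p = 0.222). Prl was at 95396 ± 124382 and 7308 ± 4830 (log2 change -2.94, SE 1.32, adjusted p = 0.157). Without 35-day replicate 1, Gh1 and Prl passed (adjusted p = 0.0414 and 0.0319), as they did in DESeq2 (0.00889 and 0.00339), and Prl with library weights (0.0375). By library the mean level of the anterior lobe list was 7.93 to 11.3 at 35 days, highest in replicate 3, and 6.92 to 8.39 at 125 days (exact permutation p = 0.114, adjusted 0.16). The anterior lobe list passed camera at adjusted p = 3.23e-04, with adjusted p = 0.546 with an estimated correlation. Of 9 intermediate lobe markers 2 rose and 2 fell (3 and 2 adjusted over the list alone; 2 and 2 without 35-day replicate 3; camera adjusted p = 0.577, with the median at 0.26 and the mean at -0.13). Gpr83 (log2 change -2.90, SE 0.38) and Neurod1 (-1.46, SE 0.30) fell, and Pcsk2 and Oacyl rose 0.79 (SE 0.19) and 0.57 (SE 0.17). The Neurod1 and Oacyl calls were lost with the anterior lobe covariate, at log2 changes of -0.88 (SE 0.30, adjusted p = 0.0754) and 0.25 (SE 0.16, adjusted p = 0.340), and that of Oacyl also without any 1 library but 35-day replicates 1 and 3 (0.0742 to 0.0951). Pomc was at 2544110 ± 798474 and 4556620 ± 767479 (log2 change 0.87, SE 0.57, adjusted p = 0.333), and passed in limma without trend (0.0286), edgeR (0.0478) and DESeq2 (0.00127).

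**Figure D4:**
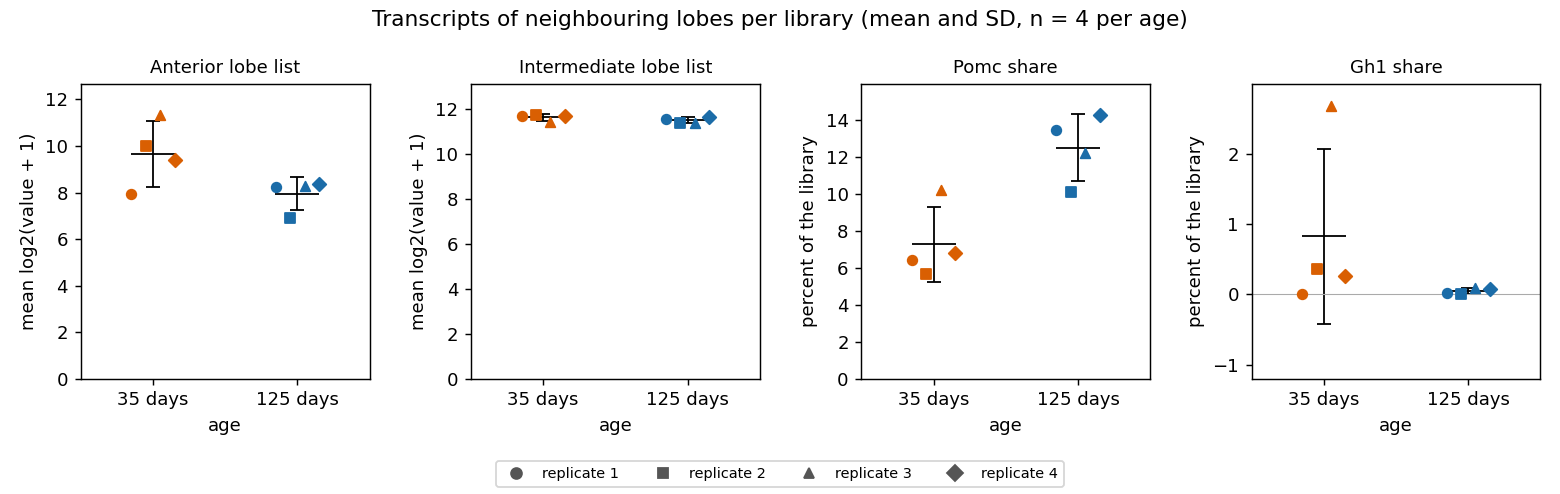
Level of the anterior lobe and intermediate lobe lists (mean log2(value + 1)) and share of Pomc and Gh1 (percent of the library) by age, with a symbol for each replicate number and the mean and SD (n = 4) in black. Replicate 3 of 35 days has the highest anterior lobe level (11.3) and Gh1 share (2.68%), and the Pomc share is 10.1 to 14.3% at 125 days.

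Red blood cell genes fell in 10 of 14 (12 adjusted over the list alone; 11 without 35-day replicate 3), with Hemgn at -3.50 (SE 0.29), Hbb-b1 at -2.21 (SE 0.28) and Ahsp at -1.84 (SE 0.20). The animals were perfused before dissection, and the camera adjusted p was 3.20e-08, with adjusted p = 0.337 with an estimated correlation. Oligodendrocyte and Schwann cell markers fell in 5 of 19 and Myrf rose (5 and 1 adjusted over the list alone; 6 and 1 without 35-day replicate 3; camera adjusted p = 0.00324, and adjusted p = 0.48 with an estimated correlation). The myelin genes Mag (log2 change -2.85, SE 0.54), Ugt8 (-1.18, SE 0.28) and Pmp22 (-0.79, SE 0.16) fell. Mag had low counts, 21.9 ± 16.6 and 2.04 ± 1.91, so the size of its fall rests on few reads. Myrf rose 0.99 (SE 0.21), and both the Ugt8 and Myrf calls were lost with the anterior lobe covariate. There Ugt8 had as large a change with a larger SE (-1.22, SE 0.38, adjusted p = 0.0587) and Myrf a smaller change (0.53, SE 0.18, adjusted p = 0.0764), and the call of Ugt8 was lost also without 125-day replicates 3 (0.0564) or 4 (0.0599). Of 14 ciliated and ependymal markers Dynlrb2 fell (-0.69, SE 0.20), a call lost with the covariate (log2 change -0.55, SE 0.27, adjusted p = 0.196) and without any 1 library but 35-day replicates 2 and 3 (0.0513 to 0.119). Adjusted over the list alone no ciliated marker passed in limma, and 2 fell without 35-day replicate 3 (camera adjusted p = 0.354). The levels of the fibroblast, lymphocyte and granulocyte, oligodendrocyte and red blood cell lists did not overlap between ages (exact permutation p = 0.0286, the smallest possible, adjusted 0.1), and no list level passed after adjustment.

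Among genes with a symbol and a mean of at least 100, the largest rises without overlap were those of Cpne4 (log2 change 5.84, SE 0.31), from 10.3 ± 4.12 to 643 ± 211, and Dpp10, an auxiliary potassium channel subunit gene (5.16, SE 0.40). Chia, a chitinase gene, went from 2047 ± 515 to 36249 ± 11723 (4.12, SE 0.26), followed by Kcnip1 (3.58, SE 0.33), B4galnt1 (3.25, SE 0.37), Lyc2 (3.13, SE 0.51), Wnt10a (3.10, SE 0.49) and the peptide gene Nmb (3.06, SE 0.36). By the same rule the largest falls were those of Asb15 (-7.44, SE 0.47), from 687 ± 155 to 3.78 ± 3.23, Fam111a (-6.55, SE 0.30), from 3838 ± 1478 to 37.3 ± 4.80, and Lhb. Alox15 (-4.47, SE 0.42), Ephx2 (-3.60, SE 0.32), Depdc1 (-3.58, SE 0.22), Knstrn (-3.51, SE 0.28) and Tcam1 (-3.48, SE 0.21) followed. Of the 3174 genes called, 2923 did not overlap between ages. These genes were called for their difference between ages, so that separation is largely built in and is no separate evidence.

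Camera with its preset correlation called 14 of the 26 lists, 4 up and 10 down, and 1 list, that of proliferation, with an estimated correlation. With the preset correlation, splits of the libraries that mixed the ages called 3 to 15 lists. Age was the only labelled difference between the groups, and the labels give no litter or date to set beside it.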

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

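The tests on 35-day replicate 3 and on lobe tissue and the counts over other splits of the libraries were chosen after the results were seen, as was the fit on 5 libraries. In 258 groups of 4 libraries (named genes, list levels and library measures), 23 had a library far from the other 3 by Dixon's test at the 95% level, against 12.9 expected by chance. Of these, 9 were in 35-day replicate 3 and 8 in 125-day replicate 2.

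In 35-day replicate 3, the level of the intermediate lobe list was 11.4 (others 11.7 in each), Gh1 was at 975243 (others 3922 to 124177) and Pomc at 3724080 (1957150 to 2248920). Neurod1 was at 209 (79.6 to 90.9), Pcsk2 at 12949 (21432 to 22669), Aqp4 at 2580 (4483 to 4673), Lyc2 at 54.5 (13.4 to 17.5), Wnt10a at 116 (17.0 to 32.0) and Sprr1a at 1.09 (others at 0). In 125-day replicate 2, the anterior lobe level was 6.92 (8.22 to 8.39), Lum was at 3433 (2069 to 2145), Lyve1 at 553 (368 to 396), Mag at 4.89 (0.978 to 1.26) and Myrf at 703 (441 to 480). In the same library Pdyn was at 5487 (6667 to 6842), Pmp22 at 3494 (2467 to 2634) and Ramp2 at 689 (397 to 440). The other 6 were Cplx1 and Mag in 35-day replicate 2, at 200.5 (others 250.04 to 258) and 46.5 (10.2 to 16.3), C4a in 35-day replicate 4, at 1068 (772 to 812), RT1-T24-1 in 125-day replicate 1, at 9.14 (23.5 to 25.4), and Cplx1 and Fosb in 125-day replicate 4, at 567 (409 to 433) and 1832 (913 to 985).

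Replicate 3 of 35 days stood apart, with 690 genes more than 1 log2 above and 1167 more than 1 log2 below the mean of the other 35-day libraries. Its anterior lobe list was 2.21 log2 above them, rank 1 of 26 lists, so anterior lobe tissue may be part of it. Ribosomal protein genes were also shifted, by a median of 0.76 log2 over 69 genes, and the respiratory chain list by 0.66, so a shift in RNA quality may be another part. Both stay open, and no biological explanation was tested.

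At 125 days, 28 of 40 matrix genes, 13 of 18 endothelial, 10 of 15 mural and 6 of 22 pituicyte markers were lower, with Myh11 and Crym higher. Pomc took a larger share there (10.1 to 14.3%, against 5.65 to 10.2%), so more intermediate lobe tissue could have diluted them. The 10.2% was that of 35-day replicate 3. Its anterior lobe level was the highest (11.3) and its intermediate lobe level the lowest at 35 days (11.4), so the Pomc share need not follow intermediate lobe tissue alone. Pomc did not pass in limma (adjusted p = 0.333) but passed as higher in limma without trend (0.0286), edgeR (0.0478) and DESeq2 (0.00127). The level of the intermediate lobe list differed by -0.12 (exact permutation p = 0.171) and by 0.314 as a mean of z-scores, so its direction depends on the scaling. The matrix list fell 0.53 log2 further than the pituicyte list (difference -0.53, exact permutation p = 0.0286, the smallest possible). Dilution by tissue without transcripts of either list would lower both lists equally. Whether intermediate lobe tissue holds transcripts of the pituicyte list was not measured, so this difference cannot decide on dilution. For the endothelial and mural lists the difference was -0.15 (exact permutation p = 0.143), and dilution cannot be told apart from a change in vessels, since they fell about as far as the pituicyte list. Anterior lobe tissue in the 35-day libraries is argued against as the whole cause, since with that level as a covariate the highest of the 4 list medians was -0.68. Age itself stays open for all of them. Only intermediate and anterior lobe tissue were weighed here. Ibsp, encoding bone sialoprotein (128 ± 62.4 and 3.85 ± 2.19), and 10 of 14 red blood cell genes (0 higher) were also lower at 125 days. Any further tissue in the 35-day libraries was not tested as a source.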

How the results depend on the processing

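The fit on the 5 libraries with the lowest anterior lobe level, and camera with an estimated correlation without 1 library, were chosen after seeing the data. Of 3046 combinations of a named gene and a setting, 2829 kept their side of the threshold and 208 in 48 genes lost the call. Another 9 in 4 genes (Gh1, Prl, Pomc and Tyms) gained it. With a call in either fit, 0 changed direction. A change of sign without a call was not counted, as for Rax (-0.11, and 0.01 without 35-day replicate 3). Library weights gave 7892 genes (3973 higher, 3919 lower), with 35-day replicate 3 weighted least. A mean of at least 50 left 823 genes changed at least 2-fold, with fewer genes tested. Leaving out 1 library gave 1894 to 5495 genes (860 to 2846 higher, 1032 to 2649 lower), highest without 35-day replicate 3; the cause was not tested. DESeq2 gave 4196 and edgeR 3170. The anterior lobe covariate gave 2758 genes, 1947 of them shared, and ended 26 named calls. The 5 libraries gave 2819 genes (1621 higher, 1198 lower), 1779 shared, and ended 38 named calls, among them all 4 endothelial and all 4 mural ones (adjusted p = 0.0601 to 0.180). These 5 libraries were picked by a measured level and leave 1 library at 35 days, assumed to vary like those of 125 days. Egfl7, Ramp2 and Erg were at -0.59, -0.67 and -0.67 there and Pecam1 at -0.98. The mural genes Kcnj8, Higd1b, Acta2 and Tagln were at -1.14, -1.06, -0.65 and -0.55 there. With all libraries these 4 were at -1.26, -1.10, -0.69 and -0.91, and the cause of the lost calls was not tested. Camera with an estimated correlation called 1 list, in place of 14 (0 to 1 without 1 library), and fry 11. The respiratory chain list turned from down to up without 35-day replicate 3 (adjusted p = 0.0411), with 0.0176 to 0.540 when leaving out 1 library; the cause was not tested. Median-of-ratios rescaling multiplied every library by 1 factor and could move nothing.

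The replicate numbers did not pair the libraries: same-number correlations were 0.044, 0.167, -0.00019 and -0.116, and 2 of 8 libraries correlated best with their own number. With the number as a block, 2718 genes passed (1290 higher, 1428 lower, 1216 at least 2-fold) and 14 lists, and the block ended the calls of 9 named genes: Nfil3 (0.105), Cyp51 (0.0606), Stard4 (0.05003), Dynlrb2 (0.0505), Vgf (0.0569), Stx1a (0.0504), Hgf (0.0574), Aldh1a2 (0.0532) and RT1-N3 (0.0603). Depth left only a bound for Ifit1, which was at 0 in all 4 libraries of 125 days.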

Other observations

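Apart from the neighbour, imprinted gene and potassium channel tests, the tests here were chosen after the results were seen. Among 24 genes that differed at least 16-fold without overlap between ages, 16 were lower and 8 higher at 125 days. Besides those named among the largest changes, Mcpt2, a mast cell protease gene with near-identical copies, had a log2 change of -6.55 (adjusted p = 5.33e-06), from a mean of 113 to 0.244. Ibsp, encoding bone sialoprotein, was at 128 ± 62.4 and 3.85 ± 2.19, and Cyp4a3 at 52.1 ± 19.8 and 0.508 ± 1.02 (n = 4 each). These 3 were chosen after their values were seen.

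Of the splits of the 8 libraries into 4 and 4, 1 of 35, the real one, gave as many genes called (3174, highest other 146). For genes changed at least 2-fold it was again 1 of 35 (1244, highest other 31). For genes called at 16-fold or more without overlap, counted anew over all genes in each split, it was 1 of 35 (24, highest other 0). Chance is thus unlikely for these counts, but 1 of 35 is the smallest share such splits can give. Every other split mixes the ages in both groups, which can itself lower its counts. For the lists past camera, 2 of 35 splits gave as many (14, highest other 15), so chance cannot be excluded for that count. The split with 15 grouped 35-day replicates 1, 2 and 3 with 125-day replicate 2, so it kept part of the age difference. With 2 libraries of each age on each side, up to 13 lists were called. All splits but the real one called 3 to 15 lists, most of them with 0 genes called. A camera call with the preset correlation alone is therefore weak evidence of an age difference.

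Inherited differences between the rats of the 2 ages may account for part of the 24 genes, since a linked variant could also move their neighbours. The 3 tested genes on each side had a median absolute log2 change of 0.30, against a median of 0.23 in 10000 draws of genes matched on level (percentile 97.48). That test placed 20 of the 24 genes (83.3%) in the order of assembly GRCr8. A first matching by symbol and synonym placed 18 (75%), too few to use (percentile 98), and identifiers were matched further after that was seen. Genes regulated together with age could give the same neighbour change, so age stays open, and no litter or supplier is labelled. Tissue or cell content was not tested for the 24 genes, which include the anterior lobe marker Lhb and the mast cell gene Mcpt2.

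A lower interferon response at 125 days is argued against as the cause of Ifit1 at 0, since the other 31 listed genes had a median log2 change of 0.23. A shared fall of imprinted growth genes with Igf2 was left undecided: of 9 others measured, 3 fell (Grb10 at -1.21, H19 at -2.86 and Ndn at -0.64) and Plagl1 rose 1.31 (4 and 2 without 35-day replicate 3), the Ndn call being lost with the anterior lobe covariate (log2 change -0.41, SE 0.15, adjusted p = 0.0867). A shared rise of A-type potassium channel subunits with Dpp10 and Kcnip1 was also left undecided: of 7 others, 3 rose (Kcnd3 by 1.70, Kcnd2 by 0.69 and Kcnip3 by 0.71) and Kcnip2 fell by 0.58 (4 and 1 without 35-day replicate 3). The Kcnd2 call was lost without 35-day replicates 1 or 2 or 125-day replicates 3 or 4 (0.0506 to 0.0666), and that of Kcnip3 without 35-day replicates 1 or 2 or 125-day replicates 1 or 3 (0.0521 to 0.0708). All 13 mitochondrially encoded genes had negative estimates, with a median of -0.34, and limma called 0 of them, with 3 lower at an unadjusted p below 0.05; edgeR called 2 lower and DESeq2 4, so lower mitochondrial transcripts at 125 days were left undecided.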
